A study of Hemerocallis lilioasphodelus with 26 samples.

How the data were processed

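Small RNAs of daylily (Hemerocallis lilioasphodelus) had been sequenced from 13 libraries of field-grown plants: 1 of leaf, 1 of whole floral bud, 6 of anther and 5 of pistil. The other 13 samples of the series, of messenger and full-length RNA, had no count file of this kind and were not analysed. Per the labels, the authors size-selected small RNAs on a gel and made the libraries with a TruSeq kit. The deposited files give a count of reads for each distinct sequence (a tag) from 18 to 34 nt. How adapters were trimmed was not stated for these files. The libraries held between 30548626 and 68247257 reads, and every level is given in RPM, the count scaled by the total reads of that library, as CPM is.

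No daylily genome was at hand, so neither tags nor assembled contigs have a genomic position. Each anther or pistil library is another stage of the flower, so a p-value for anther against pistil measures the spread between stage libraries, not between plants of one stage. Leaf and bud have no replicates. Replicate numbers follow the order of deposit: anther replicates 1 to 6 run from the shortest to the longest anther and pistil replicates 1 to 5 are stages 0 to 4. PCR reads are not independent molecules, so the exact 95% intervals and the floors, which are 3 reads of the library, cover counting error only. The intervals are exact Poisson ones for family levels in leaf and bud and Clopper-Pearson ones otherwise. The floor lay between 0.0440 and 0.0982 RPM per library, at 0.0119 RPM over all anthers and at 0.0118 RPM over all pistils.

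Shares of reads by length, 5' base and duplex overlap were compared by exact two-sided permutation tests over all 462 splits of the 6 anthers and 5 pistils. Adjustment was by Benjamini-Hochberg over 5 length classes, 12 base shares and 2 duplex classes. The duplex measure was the share of distinct tags with at least 2 reads, in libraries thinned to one depth, that had a partner of the opposite strand at the offset a Dicer product would have (22 shared bases for 24 nt, 19 for 21 nt). The share at an overlap 2 nt shorter was subtracted as background. The 24-nt share was correlated with the upper anther length over all 720 pairings.

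Families of microRNA were counted from tags of 20 to 22 nt whose first 19 bases differed by at most 2 substitutions from a reference of that family and by more from any other. References for 31 families and 5 families absent from monocots or from plants were written from background knowledge. Counts per family, per tag and per contig were tested with edgeR 4.0.16 under R 4.3.3 (quasi-likelihood, limma 3.58.1), with the total reads as library size and no further scaling, at a false discovery rate of 0.05. A family needed 10 reads in 3 libraries and a tag of 20 to 24 nt needed 10 RPM in 3 libraries. Slopes on anther length (6 anthers) and on stage number (5 pistils) used the same model. In simulated libraries with the spread of the real ones, in which 200 of 6301 tags were changed, 42% of the 4-fold decreases and 22% of the 4-fold increases were called, against 2% and 0% of the 2-fold ones, with 0% false calls.

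Contigs of at least 96 nt were assembled from tags with at least 5 pooled reads (k of 19) and tested for a register of 24 nt or 21 nt, the lower strand shifted by 2 nt, against 10000 shuffles of the counts over positions, and in 1 alternative 100000. In simulated precursors, assembled with k of 19, 100 of 100 phased and 3 of 200 unphased contigs were called. These rates do not carry over to the 4th assembly below, whose contigs had a median length of 113 nt. The planned assembly gave 23 contigs. Assemblies with k of 17 and with at least 10 reads per tag gave 38 and 12. A 4th assembly, with k of 17 and with branches ignored at 0.5 or less of the best branch, gave 1122 contigs with at least 5 covered positions and 50 reads of 24 nt, and the contig results come from it.

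The families named are all past the threshold, up to 20, and all of the lists of reproductive phasiRNA triggers and of the small RNA pathway. In leaf, a family is named if it lay at least 4-fold above or below each anther and pistil library. The tags named are the 3 with the largest change in each direction past the threshold and a mean of 100 RPM in the higher group (for slopes, in any library). The contigs named are the 3 with the largest change in each direction and the 3 with most reads.

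Tests, family lists, named items and 53 alternatives were fixed before the data were examined. The dominant-branch assembly, its 100000 shuffles, the test of all its contigs, the family slopes, the fits of stages 0 to 2 without a block, and the alternative without the kit's stop oligo (at most 2 substitutions from its 22 nt) were added after the data had been seen. The oligo's sequence also came from background knowledge. Alternatives were edgeR's TMM factors, DESeq2 1.42.0, other filters and matching rules, the stage-named libraries alone, stage as a block, and each library left out. Shares and permutation tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures used matplotlib 3.10.9.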

Results

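The series asked which small RNAs of the reproductive pathways accumulate in daylily anthers before and during meiosis. Anthers were sampled at lengths of <1.0 mm, 1.5-2.0 mm, 2.5-3.0 mm, 3.3 mm, 4.1 mm and 5.8 mm, the last 3 also named stages 0 to 2, and pistils at stages 0 to 4. A leaf and a whole bud with anthers of <1.0 mm completed the set. In the order leaf, bud, anthers and pistils, the libraries held 39246683, 37633128, 52387534, 30548626, 41161532, 48546267, 45773743, 32982067, 45534573, 50177784, 35155630, 68247257 and 55651517 reads. Distinct tags numbered between 5495062 (leaf) and 17414997 (pistil stage 3).

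The bud and the 3 anthers named by length alone formed a separate batch in the files. Their tags were sorted by count, 0.0141% to 0.0150% of their reads held an undetermined base, and 34-nt reads made up 1.58% to 2.10% of each. In the other 9 libraries no tag held such a base and 34-nt reads made up at most 0.0486%. Tags equal to the stop oligo of the library kit, a reagent, or within 2 substitutions of it took 2.97% to 4.20% of the reads of the first 4 libraries and 0.00453% to 0.0173% of the others. All short anthers were in the first batch and all pistils in the second, so values within the stage-named libraries (3 anthers, 5 pistils) are given beside the pooled ones.

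Small RNAs of 24 nt, the length of heterochromatic and of reproductive 24-nt small RNAs in plants, were the most abundant class in flowers. They made up 37.4% ± 4.46 (SD, n = 6) of anther reads and 42.8% ± 4.84 (n = 5) of pistil reads. Reads of 22 nt followed with 16.6% ± 1.88 in anther and 15.5% ± 3.18 in pistil, and those of 21 nt held 8.24% ± 0.788 and 8.77% ± 0.845. The stop oligo made up 18.95%, 16.59% and 20.88% of the 22-nt reads of the length-named anthers, from the shortest on. In the other anthers and the pistils it made up at most 0.0103%. Without the oligo the 22-nt shares of the length-named anthers were 16.58%, 13.72% and 14.45%. The higher 22-nt mean in anther thus includes reads of a reagent. In leaf the order was different, with 21.3% of reads at 21 nt and 18.0% at 24 nt, while the bud held 44.4% at 24 nt. The exact 95% intervals of the 24-nt share ran from 17.945% to 17.969% in leaf and from 44.3684% to 44.4002% in bud. By exact permutation 0 of the 5 length classes passed the threshold for anther against pistil, also 0 at an unadjusted p under 0.05: the 24-nt difference was -5.42 points (p = 0.0952, adjusted p = 0.238) and -4.96 points within the stage-named libraries (p = 0.179).

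**Figure D1:**
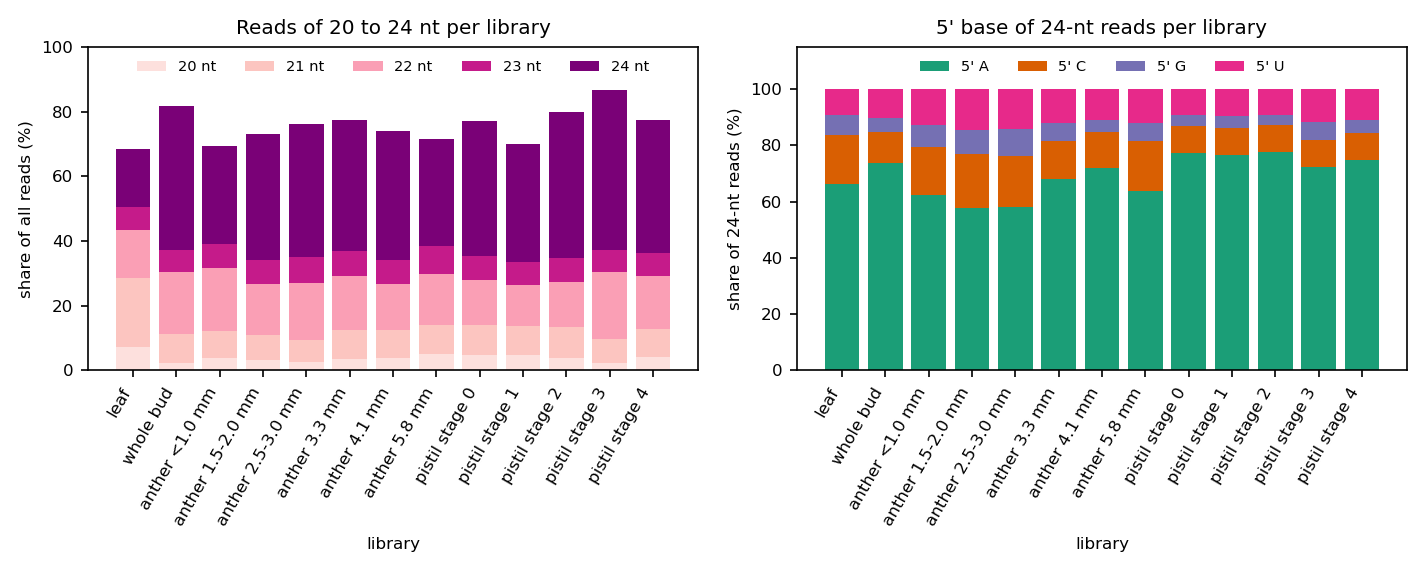
Share of all reads (percent, vertical axis) at each length from 20 to 24 nt, stacked per library (horizontal axis). Another panel shows the share of 24-nt reads with each first base per library. The 24-nt class averages 37.4% in the 6 anthers and 42.8% in the 5 pistils, and is 18.0% in leaf and 44.4% in bud.

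Along the anther series the 24-nt share was 30.5% at <1.0 mm, 38.9%, 41.3% and 40.5% at the next lengths, 39.9% at 4.1 mm and 33.1% at 5.8 mm. As a share of reads it had no relation to length past the threshold in these 6 anthers (Pearson r = 0.105, exact permutation p = 0.851, Spearman rho = 0.2, p = 0.714). Without the pair of anthers farthest from the median length r was 0.417. The relation hung on the ends of the series, since r was -0.759 without anther replicate 1 and 0.817 without anther replicate 6. The stage-named batch held only 3 anthers, too few for a correlation of its own. Counted over distinct tags, r was 0.836 (exact permutation p = 0.0417, rho = 0.8286, p = 0.0583).

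The first base of a small RNA goes with the Argonaute protein that binds it. Among 24-nt reads, a 5' A was carried by 63.6% ± 5.56 (SD, n = 6) in anther against 75.7% ± 2.19 (n = 5) in pistil, while a 5' C was carried by 16.5% ± 2.51 against 9.65% ± 0.118 and a 5' U by 12.7% ± 1.33 against 10.1% ± 1.16. Among 21-nt reads, a 5' U, typical of microRNAs, was less frequent in anther (38.0% ± 3.02 against 44.5% ± 4.51), and 5' C (33.4% ± 2.26 against 29.1% ± 2.19) and 5' G (9.90% against 8.25%) were more frequent. These 6 of the 12 shares differed by exact permutation, with adjusted p = 0.026 for 24-nt A and C and 0.0303 for the other 4. Within the stage-named libraries 24-nt A differed by -7.93 points (exact p = 0.0179, the smallest that 56 splits allow, adjusted p = 0.107) and 0 of the 12 shares passed, with 2 (24-nt A and C) at an unadjusted p under 0.05. Leaving out 1 library gave between 0 and 8 shares past the threshold: 0 without pistil replicate 3 or 5, 2 without anther replicate 1, 2, 3 or 6 and 3 without pistil replicate 4.

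Dicer products pair with a partner on the other strand with 2-nt overhangs. The excess of such 24-nt pairs over background was above 0 in the anthers of 1.5-2.0 mm (0.557 percentage points) and 2.5-3.0 mm (0.142) and below 0 in the other 11 libraries. The background overlap needs 2 fewer matching bases, so a value below 0 does not show that such pairs are absent. The mean excess was -0.218 ± 0.464 (SD, n = 6) in anther and -0.733 ± 0.133 (n = 5) in pistil. For 21-nt tags the means were -0.239 ± 0.172 and -0.650 ± 0.0624. Both differences passed the exact permutation test, with 0.515 points for 24 nt (adjusted p = 0.0173) and 0.411 points for 21 nt (adjusted p = 0.00866). Within the stage-named libraries the 21-nt difference was 0.382 (exact adjusted p = 0.0357) and the 24-nt one 0.266 (exact p = 0.0714), and 1 of the 2 classes passed. From tags with at least 5 reads the values at 1.5-2.0 mm and 2.5-3.0 mm were 1.92 and 0.817 points, and the 21-nt excess was above 0 in 5 of 6 anthers (0.0812 to 0.272, and -0.221 at <1.0 mm) and below 0 in the 5 pistils, so the sign of an excess depended on that minimum. Both differences passed with it as well (0.835 and 0.380 points, exact adjusted p = 0.0325 and 0.0130). One class also passed without pistil replicate 1, 2, 3 or 5.

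Of 31 microRNA families and related small RNAs, 24 had enough reads to test and 8 differed between anther and pistil, 5 higher and 3 lower in anther. With TMM factors 12 differed (5 higher, 7 lower), with DESeq2 13 (10 higher, 3 lower) and within the stage-named libraries 13 (8 higher, 5 lower). The median log2 fold change of all 24 families was 0.90 as tested and 0.35 with TMM factors. All 8 kept their call in each of these 3 alternatives. Without anther replicate 1 there were 13 (9 higher, 4 lower), with the 8 among them, and without any other library 8 or 9. Counted from tags without substitution, miR2275 and miR395 had too few reads to test and the other 6 kept their call.

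Of the triggers of reproductive phasiRNAs, miR2275, which in grasses starts the 24-nt phasiRNAs of the anther, was 6.89 ± 0.88 (log2, SE) higher in anther. It stood at 10.0 ± 5.16 RPM (SD, n = 6), between 4.76 and 19.5, against 0.0846 ± 0.0652 in pistil (n = 5; edgeR adjusted p = 5.49e-05; 6.27 ± 0.84 within the stage-named libraries, adjusted p = 0.000196). The bud held 3.88 RPM and the leaf 1 read. Its most frequent tag, TTTAGTTTCCTCCAATATCTCA, held 15.5% of the family's reads and differed from the reference by 1 substitution. The other trigger family, that of miR2118 and miR482, which starts 21-nt phasiRNAs, had 4 reads, all in the 3.3 mm anther, which also held reads of families not known from monocots, and was not tested. Adjusted over the list alone, 1 of the 2 trigger families differed.

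In the nutrient list, 3 of the 5 tested families were higher in anther and 0 were lower, also when adjusted over the list alone. The copper-responsive miR408 stood at 19.4 ± 22.8 RPM (SD, n = 6) in anther against 0.318 ± 0.171 in pistil (n = 5; log2 5.92 ± 1.38, edgeR adjusted p = 0.00348; 6.73 ± 0.77 within the stage-named libraries, adjusted p = 6.94e-05), with 0.153 RPM at <1.0 mm and 54.4 at 4.1 mm. The sulfate-responsive miR395 had 382 anther reads and 1 pistil read, a ratio of 387 with a counting interval from 69.1 to 15329.8 (log2 7.66 ± 1.86, edgeR adjusted p = 0.00416; 8.55 ± 1.38 within the stage-named libraries, adjusted p = 0.000659). It was at 0 in the anther of <1.0 mm, below a floor of 0.0573 RPM, and highest at 3.3 mm (4.37 RPM). The 3.3 mm anther, which also held reads of families not known from monocots, had 212 of the 382 reads, and the 4.1 mm anther had 136. The phosphate-responsive miR399 stood at 0.950 ± 0.863 against 0.0153 ± 0.0180 RPM (log2 5.70 ± 1.27, edgeR adjusted p = 0.00294; 3.44 ± 1.13 within the stage-named libraries, adjusted p = 0.0267). Its main tag lay 2 substitutions from the reference, and the call ended in stages 0 to 2 without a block (edgeR adjusted p = 0.133). The anthers of 3.3, 4.1 and 5.8 mm held 24, 1 and 2 of its reads, against 75, 60 and 71 in the length-named anthers. Each pistil library held 0 to 2. The stage-named value of miR399 thus rests mainly on the 3.3 mm anther, which also held reads of families not known from monocots. miR398 (8.40 against 2.78 RPM) and miR827 (4.94 against 2.05) did not pass.

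In the development list, 3 of the 13 tested families differed, also when adjusted over the list alone. miR159, which targets MYB factors of the anther and seed, was lower in anther at 354 ± 83.4 RPM (SD, n = 6) against 3983 ± 757 (n = 5; log2 -3.49 ± 0.24, edgeR adjusted p = 1.43e-07; -3.56 ± 0.34 within the stage-named libraries, adjusted p = 2.77e-05). The related miR319, which targets TCP factors, was at 114.9 ± 66.3 against 1330.1 ± 555 RPM (log2 -3.53 ± 0.56, edgeR adjusted p = 0.000293; -4.22 ± 0.75 within the stage-named libraries, adjusted p = 0.000741). miR167, which targets auxin response factors needed for anther and ovule maturation, was higher at 1390 ± 1183 against 130 ± 33.4 RPM (log2 3.42 ± 0.59, edgeR adjusted p = 0.000513; 4.08 ± 0.40 within the stage-named libraries, adjusted p = 2.77e-05). The remaining 10 families, among them miR166 (4711 against 5229 RPM), miR396 and miR160, did not pass.

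Of the 5 families of the small RNA pathway, 1 differed, also when adjusted over the list alone. tasiARF, the trans-acting small RNA that targets auxin response factors, was lower in anther at 21.1 ± 9.11 RPM (SD, n = 6) against 99.3 ± 28.8 (n = 5; log2 -2.23 ± 0.40, edgeR adjusted p = 0.000513; -2.70 ± 0.48 within the stage-named libraries, adjusted p = 0.000741). miR390, which starts its production, was at 10.4 ± 5.43 against 20.0 ± 5.12 RPM (edgeR adjusted p = 0.140). miR168, which targets an Argonaute messenger, was at 27.99 ± 6.94 against 41.5 ± 10.1 RPM (adjusted p = 0.140) and miR162, which targets a Dicer messenger, at 48.4 ± 8.00 against 63.1 ± 17.2 RPM (adjusted p = 0.248). miR403 averaged 2.18 RPM in anther and 1.08 in pistil (adjusted p = 0.615). The 3.3 mm anther held 569 of its reads, beside reads of families not known from monocots, and without that library, anther replicate 4, the log2 fold change was -2.01.

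**Figure D2:**
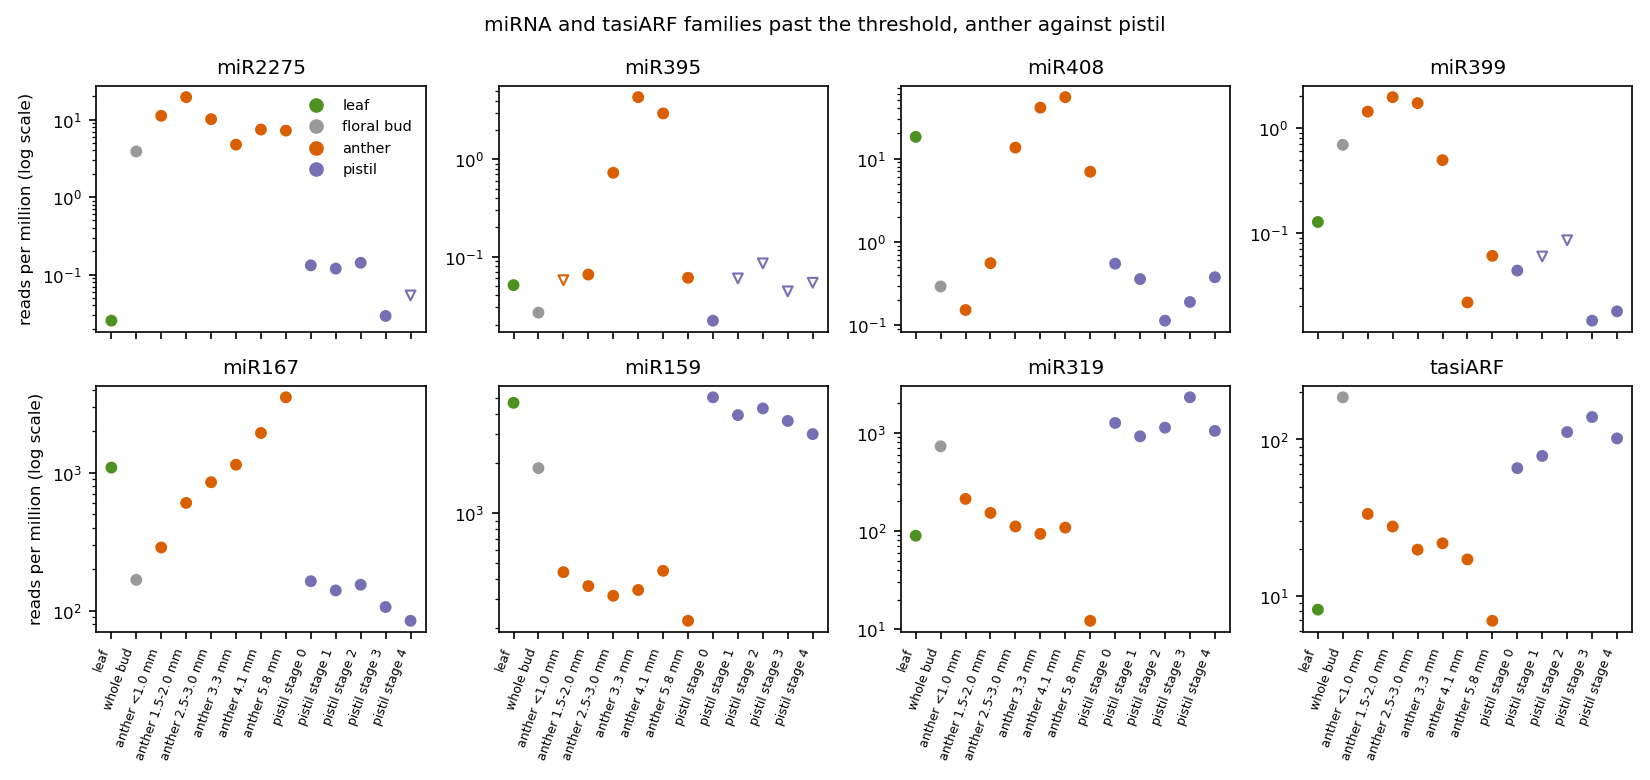
Level in RPM (log axis) of the families that differed between anther and pistil, per library. Open triangles mark libraries with 0 reads, drawn at the floor of 3 reads of that library. miR2275 lies between 4.76 and 19.5 in the 6 anthers and at or below 0.142 in the 5 pistils.

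Over anther length, 4 of 24 families had a slope. miR167 rose by 0.75 ± 0.06 (log2 per mm, SE; n = 6; edgeR adjusted p = 0.00053), from 287 RPM at <1.0 mm through 604, 853, 1142 and 1938 to 3514 at 5.8 mm. miR396, which targets growth-regulating factors, rose by 0.54 ± 0.12 (adjusted p = 0.0389), but its level was 245 to 652 RPM in 5 anthers and 2121 at 5.8 mm, and without that library, anther replicate 6, the slope was 0.31 (edgeR adjusted p = 0.230). miR160 (-0.61 ± 0.14, adjusted p = 0.0389) and tasiARF (-0.45 ± 0.11, adjusted p = 0.0437), both directed at auxin response factors, fell. With the naming series as a factor only miR167 passed among the 24 families (0.68 per mm, edgeR adjusted p = 0.0233). The slopes of miR396 (0.74 ± 0.20) and tasiARF (-0.56 ± 0.15) were not smaller with that factor but their errors were larger (edgeR adjusted p = 0.131 for each), while that of miR160 was -0.39 ± 0.21 (adjusted p = 0.320). In the model without it, DESeq2 called 14 families. Without anther replicate 1 or 3 there was 1 call, without replicate 2 there were 2, and without replicate 6 there were 6, with miR167 among them each time.

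Over pistil stage 1 family had a slope. miR393, which targets auxin receptors, rose by 0.65 ± 0.18 (log2 per stage, SE; n = 5; edgeR adjusted p = 0.0436), from 30.5 RPM at stage 0 to 204 at stage 3 and 135 at stage 4. Its call ended without pistil replicate 1, 2, 3 or 4 (edgeR adjusted p = 0.859, 0.320, 0.0573 and 0.0925) and with TMM factors (0.0705), and held without replicate 5 (5.12e-05). With TMM factors 0 families passed (5 at an unadjusted p under 0.05), with DESeq2 5, without replicate 2 or 4 there were 0 and without replicate 5 there were 2. The slopes over stages 0 to 2 differed between anther and pistil in 0 of 24 families by edgeR, with 5 at an unadjusted p under 0.05.

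Single tags differed widely between the tissues. Of 6301 tags tested, 1983 differed, 808 higher and 1175 lower in anther. Of the 2948 tags of 24 nt, 516 were higher and 1067 lower, and of the 1105 tags of 22 nt, 140 were higher and 40 lower. The stop oligo and its variants made up 42 of the tested tags, all 42 higher in anther, and 32 of these were among the 22-nt tags. Without the oligo in tags and totals, 1946 of 6259 tags differed (782 higher, 1164 lower), and 1930 of these were also called with it. Within the stage-named libraries 1538 tags differed, 1442 of them shared. The median log2 fold change of all tags was -0.23 as tested and 0.01 with TMM factors, with which 2033 differed. With a filter of 50 RPM, 170 of 863 tags differed and 60% of them were higher, against 40.7% in the main test, and with 2 RPM 14888 of 35744 differed.

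Among tags higher in anther, GATAGGAGGATACAGTTAAAACTC reached 353 RPM at 1.5-2.0 mm and 230 RPM at 2.5-3.0 mm, and fell short of 1 RPM at 5.8 mm (0.970). Its mean was 108 ± 149 RPM (SD, n = 6) against 0.0264 in pistil (n = 5; log2 11.94 ± 2.02, edgeR adjusted p = 0.000289; 9.45 ± 1.46 within the stage-named libraries, adjusted p = 0.000219). The pistil value came from stage 0 alone (0.132 RPM, 0 at the other 4 stages), and without pistil replicate 1 the log2 fold change was 15.27. The 2 larger changes belonged to the stop oligo: GAATTCCACCACGTTCCCGTGG, equal to it over all 22 nt, had 25571 to 35816 RPM in the length-named anthers, 27452 in bud and 1.61 to 15.4 in the other 9 libraries (log2 12.73 ± 2.71, edgeR adjusted p = 0.00189, and 1.67 with adjusted p = 0.118 within the stage-named libraries). GAATTCCACCACGTTCCCGTG, which lacks its last base, had a mean of 159 ± 180 RPM and was at 0 in all pistils, at least 13511-fold lower by the floor over the group, but also at 0 in the 3 stage-named anthers, so the bound sets the batches apart and not the tissues. The next by the same rule, chosen after the oligo was recognised, were TATCTCTTCAAGTTCTTGGCACTG (274 ± 339 against 0.242 RPM, log2 10.14 ± 1.91, edgeR adjusted p = 0.0007; 8.57 within the stage-named libraries) and CCCTGACACATTGAATTTTTTGAA (102 ± 108 against 0.0687 RPM, log2 10.52 ± 1.64, edgeR adjusted p = 0.000139; 9.66 within the stage-named libraries). Both also stood highest at 1.5-2.0 mm, at 869 and 278 RPM.

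The 3 tags with the largest decrease in anther were all of 24 nt and began with A. ATTTGTTAGAATTCTCATGTGCCT had 0.0528 RPM in anther (n = 6) against 120 ± 73.2 in pistil (n = 5; log2 -11.15 ± 0.88, edgeR adjusted p = 2.88e-07). AGAATTCTAAGAGATTGAGGCTTG had 0.0753 against 146 ± 54.7 RPM (log2 -10.87 ± 0.90, edgeR adjusted p = 4.38e-07), and AAAACCCTTGAGTTCTCTGACAGA 0.0932 against 159 ± 49.8 RPM (log2 -10.68 ± 1.01, edgeR adjusted p = 1.25e-06). Within the stage-named libraries the log2 fold changes of these 3 were -10.61, -9.97 and -9.71.

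Over pistil stage 467 of 4584 tags had a slope, 431 rising and 36 falling, and 396 of the rising ones were of 24 nt. AAAACGCCGGTGTAGAAATGCGGG rose from 3.05 RPM at stage 0 to 180 at stage 4 (log2 1.53 ± 0.23 per stage, n = 5, edgeR adjusted p = 0.0074), and AAACTTAAACTCTGTCTAGCACCC fell from 100.2 to 5.93 RPM (edgeR adjusted p = 0.0074). ACGGTCGACCTTGAGTTTCGGC (log2 2.29 ± 0.64, edgeR adjusted p = 0.0385) and ACGGTCTACCATGAGTTTCGGC (1.71 ± 0.46, adjusted p = 0.0334) each lay 1 substitution (G7T and A11T, counted from the 5' end of the tag) from ACGGTCTACCTTGAGTTTCGGC, which stood at 19505 to 95827 RPM in the flower libraries. The count was 0 without pistil replicate 1, 146 without replicate 2 (140 rising) and 236 without replicate 3 (232 rising), while 965 without replicate 4 split into 511 rising and 454 falling and 2072 without replicate 5 into 772 rising and 1300 falling. With TMM factors 873 tags had a slope (816 rising, 57 falling). DESeq2 called 1457 tags, 68.3% of them rising against 92.3% in the main test.

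Over anther length 0 of 4136 tags passed by edgeR, with 762 at an unadjusted p under 0.05, against 1398 by DESeq2. With TMM factors the count was 0 (926 unadjusted) and with the naming series as a factor also 0 (884 unadjusted). Without anther replicate 1 it was 415.

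Contigs assembled from the tags addressed whether daylily makes loci of phased small RNAs in the anther. With 10000 shuffles 0 of 1122 contigs were phased after adjustment at 24 nt (67 at an unadjusted p under 0.05) and 0 of 1027 tested at 21 nt (33 unadjusted). The lowest p at 24 nt was 1e-04, the smallest that 10000 shuffles can give, and a lone contig could not pass with it (adjusted p = 0.112). With 100000 shuffles, tried for that reason, 2 contigs passed at 24 nt and 0 at 21 nt. Contig172 (149 nt) held 55.8% of its 24-nt reads in 1 of the 24 registers (permutation p = 2e-05, exact 95% interval over the shuffles 2.5e-07 to 5.57e-05, adjusted p = 0.0224). Contig958 (99 nt) held 56.7% (permutation p = 7e-05, exact 95% interval over the shuffles 2.2e-05 to 0.000131, adjusted p = 0.0393). Only 1 shuffle reached the share of contig172 and 6 that of contig958, so both calls rest on few shuffles. Contig172 averaged 12.4 ± 14.5 RPM (SD, n = 6) in anther against 0.0779 ± 0.0356 in pistil (n = 5; log2 7.26 ± 1.14, edgeR adjusted p = 0.000141; 6.00 ± 0.85 within the stage-named libraries, adjusted p = 0.000496), with 38.7 RPM at 1.5-2.0 mm and 0.758 at 5.8 mm. In the planned assembly 0 of 23 contigs were phased at 24 nt (1 unadjusted) and 0 of 16 tested at 21 nt (4 unadjusted).

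Without regard to phasing, 640 contigs differed between anther and pistil, 228 higher and 412 lower in anther, and within the stage-named libraries 566 (166 higher, 400 lower). The median log2 fold change of all contigs was -0.16 as tested and 0.07 with TMM factors, with which 705 differed (319 higher, 386 lower). A group of 283 contigs lay at least 8-fold lower in anther. Their summed level was 2622 RPM in the pistil at stage 0, 4289 at stage 1, 9672 at stage 2, 15373 at stage 3 and 13696 at stage 4, against 32.2 RPM in leaf, 85.4 in bud and 52.2 ± 11.7 (SD, n = 6) in anther. Contig levels count reads of 20 to 24 nt only. Reads of 24 nt made up 88.9% to 90.0% of the summed level in the pistils. Of these 24-nt reads, 77.2% to 83.1% began with A. In contrast 66 contigs lay at least 8-fold higher in anther, with 791 RPM at <1.0 mm, 2614, 5739, 5499.8 and 6881 at the next lengths and 2748 at 5.8 mm, against 128 ± 70.8 in pistil, 52.2 in leaf and 574 in bud. Between 34.3% and 80.8% of these anther reads were of 24 nt, with a 5' A in 37.8% to 60.8%. Of the anther reads of the 66 contigs, 59.2% lay in 10 contigs, so a few contigs weigh on this sum. Of the pistil reads of the 283 contigs, 21.4% lay in 10, which are a smaller part of a longer list, so these shares do not compare directly. The contigs were grouped by the tissue test itself, so the gap between anther and pistil follows from the choice, while the leaf and bud values do not. From pistil stage 0 to 4 the TMM factors were 1.41, 1.35, 1.14, 0.614 and 1.13, and divided by them the sum of the lower group was 1862, 3188, 8484, 25046 and 12173 RPM. Fragments of 5.8S ribosomal RNA stood at 13593, 15857, 10245, 4456 and 9877 RPM in the same libraries.

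**Figure D3:**
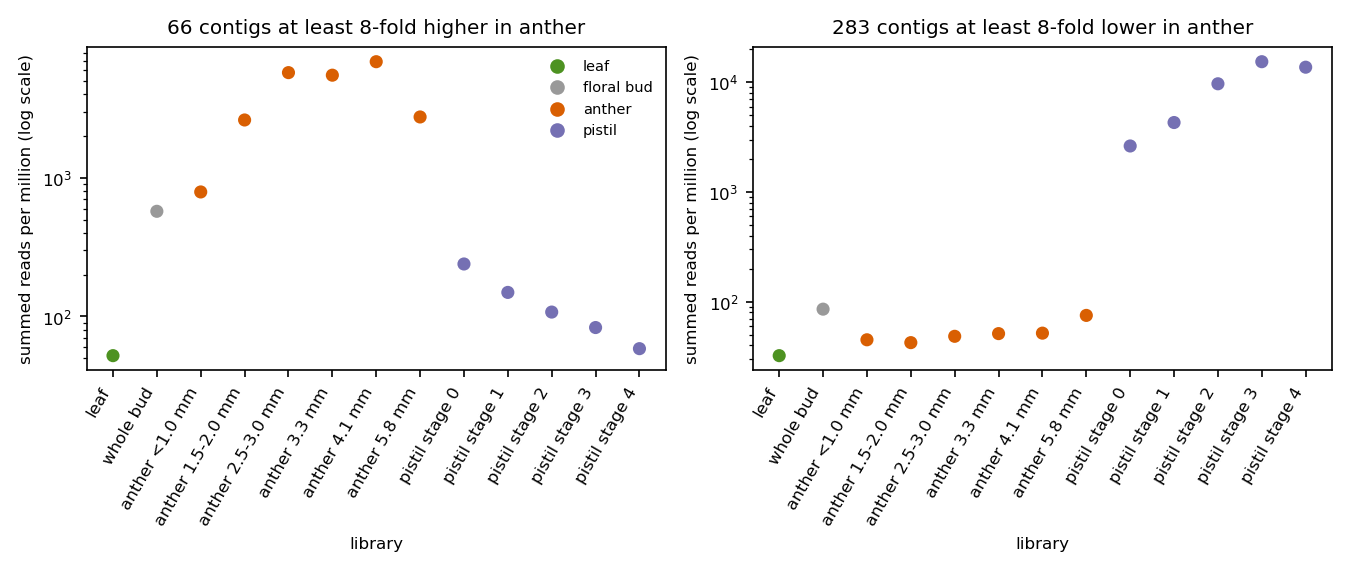
Summed RPM (log axis) per library of the 66 contigs at least 8-fold higher and the 283 contigs at least 8-fold lower in anther. The lower group runs from 2622 at pistil stage 0 to 15373 at stage 3 and lies between 42.3 and 74.9 in the 6 anthers.

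The contigs with the largest increase in anther peaked at 1.5-2.0 mm. Contig958 (99 nt) averaged 22.2 RPM in anther (n = 6) against 0.0272 in pistil (n = 5; log2 9.66 ± 1.81, edgeR adjusted p = 0.000595) and reached 76.4, contig948 (99 nt) averaged 67.0 against 0.115 RPM (log2 9.20 ± 1.77, adjusted p = 0.000753) and reached 253, and contig930 (100 nt) averaged 22.7 against 0.0679 RPM (log2 8.33 ± 1.52, adjusted p = 0.000495). Within the stage-named libraries their log2 fold changes were 7.46, 5.70 and 6.78. The 3 with the largest decrease, contig1092 (96 nt), contig793 (103 nt) and contig857 (102 nt), had 0 reads in all anthers against 13.5 ± 8.94, 11.5 ± 10.6 and 11.5 ± 7.75 RPM in pistil (n = 5). By the floor over all anthers these were at least 1134-fold, 961-fold and 960.4-fold lower, with edgeR adjusted p = 4.15e-05, 0.00042 and 5.85e-05 (0.000682, 0.00481 and 0.000896 within the stage-named libraries). The 3 contigs with most reads did not pass the threshold: contig1 (1548 nt, 28145 against 28921 RPM), contig39 (216 nt, 23881 against 29584 RPM), which holds 5.8S ribosomal RNA, and contig2 (1308 nt, 25272 against 22809 RPM).

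**Figure D4:**
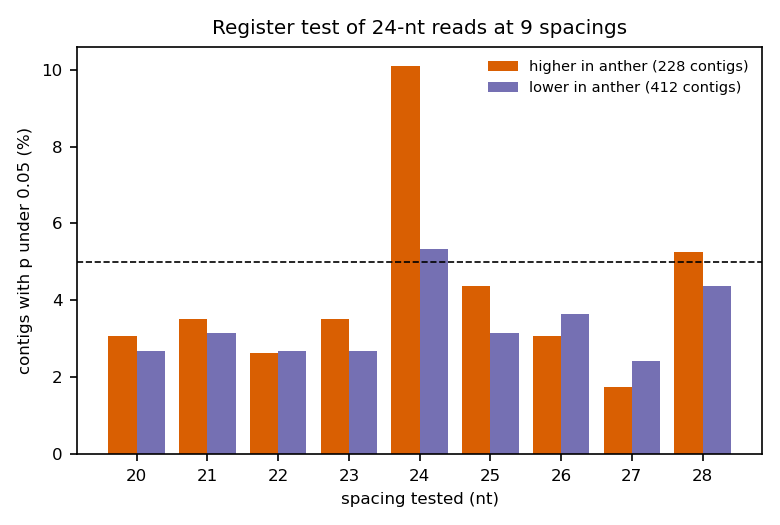
Percent of contigs (vertical axis) with an unadjusted p under 0.05 at register spacings of 20 to 28 nt (horizontal axis), for 228 contigs higher and 412 lower in anther. The dashed line marks 5 percent, and 24 nt gave 23 higher and 22 lower contigs.

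Leaf set apart 7 families from each anther and pistil library. Higher in leaf were miR166, which targets leaf polarity factors (35152 RPM, exact 95% interval 35094 to 35211, 4.61-fold above the nearest library), and miR156, which holds plants in the juvenile phase (300.2 RPM, 295 to 306, 6.25-fold). So were miR168 (353 RPM, 347 to 358, 6.68-fold) and the copper- and phosphate-responsive miR398 (392 RPM, 386 to 398, 12.98-fold) and miR827 (86.9 RPM, 84.0 to 89.8, 8.27-fold). Lower in leaf were miR390 (0.102 RPM, 0.0278 to 0.261, 19.04-fold) and miR160 (0.713 RPM, 0.474 to 1.03, 7.27-fold). Fragments of plastid psbA messenger stood at 536 RPM in leaf and at 4.94 to 13.7 RPM in the other 12 libraries. In the bud, tasiARF stood at 186 RPM (182 to 190), above each anther and pistil library.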

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

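Of the tests in this part, those of the naming series, of degraded RNA, of library composition, of the stop oligo and of anther tissue and the counts over other splits were chosen only after the results were seen.

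The 283 contigs at least 8-fold lower in anther, whose summed level was highest at pistil stage 3 among the 13 libraries, were weighed first. Of 284 contigs at least 8-fold lower in the length-named anthers than in the pistils, 283 were the same, and in the stage-named anthers, left out of that choice, the pistil mean was 151 times the anther mean, which argues against the naming series as the cause. An organism without 24-nt small RNAs would not give a lowest pistil share of 88.9% 24-nt reads. That share is of contig reads of 20 to 24 nt, and fragments of degraded RNA spread over these lengths would not give it either. Shorter and longer fragments were not counted, so the share cannot decide on degraded RNA of other lengths. The 10 contigs with most reads held 21.4% of the pistil reads, so a few contigs did not carry the sum. How many loci the contigs come from is not known, since they have no genomic position. Divided by the TMM factors, the mean of pistil stages 3 and 4 was 7.37 times that of stages 0 and 1 (4.21 times before), with a lower quartile of 5.14 over the 283 contigs, which argues against library composition as the cause of the whole rise. RNA of another plant in the pistil samples was not tested, and differences between the tissues and, with 1 library per stage, between pistil stages stay open.

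The 22-nt tag GAATTCCACCACGTTCCCGTGG was weighed second. The lowest of the 4 length-named flower libraries held 1664 times the level of the highest other library, bud included among the 4, which fits the batch and not the tissue. All 22 bases equal the stop oligo of the library kit. In the stage-named anthers the mean was 1.48 times the highest pistil, so anther tissue as the source of the change is argued against, and the equal bases fit reads of the kit's oligo.

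Reads of families unknown from monocots in the 3.3 mm anther were weighed last. miR158 stood at 4.26 RPM, miR161 at 2.18 RPM and the animal let-7 at 0.680 RPM in that library, above the floor of 0.0618 RPM, and the pistil of stage 0 also held them at 0.505, 0.307 and 0.110 RPM (floor 0.0659), and that of stage 1 held miR158 at 0.0797 and miR161 at 0.159 RPM. Of 315 reads of Brassicaceae families there, 31.4% equalled the reference without substitution, between the bounds set beforehand for reads of another organism and for loose matching of daylily reads. The 99 exact reads were 97 of the 106 of miR161 and 2 of miR173, while miR158 had 0 exact among 207 reads. Of the let-7 reads of that library, 27 of 33 were exact. The families thus differed. Of the miR161 reads, 14 of 14 at pistil stage 0 and 8 of 8 at stage 1 were also exact, which argues against loose matching for that family. miR158 had 207, 23 and 4 reads in the same libraries and 0 or 1 elsewhere, but 0 exact. Of the let-7 reads at pistil stage 0, 0 of 5 were exact. For miR158 and let-7, and for all families at once, the pair of explanations cannot be told apart. The miR403 of the 3.3 mm anther, 555 of 569 reads exact, may have the same source, and no biological explanation was tested.

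Over 100 splits of the 11 anther and pistil libraries, the real one included, only the real one called as many families, tags or contigs. Not all possible splits were drawn, and the draw took no account of the batches. A split that mixes the tissues also holds their difference as spread within its groups, which lowers its counts. The splits therefore cannot exclude chance or tell tissue from batch. Within the stage-named libraries, all of the second batch, 13 families, 1538 tags and 566 contigs differed. The real split called 8 families, 1983 tags and 640 contigs. The highest counts of the other splits were 6, 1557 and 511. The split that joined 1 anther (4.1 mm) with the 5 pistils gave the highest tags and contigs, and 6 families came from 1 split with 1 anther among the 5 pistils and 1 with 2 anthers among 4 pistils.

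Single libraries far from the others of their group were looked for in 102 groups of values, where chance alone gives about 1 in 20, that is 5.1, and 11 were found. The libraries of a group are different stages, the anthers also of both batches, and some of the values depend on each other. The 11 therefore do not show an excess over chance. In the 3.3 mm anther the values found were miR403 at 11.7 RPM and the share of 22-nt reads with a 5' A at 50.4%. In the 5.8 mm anther they were miR396 at 2121 RPM, the 283 contigs at 74.9 RPM, nuclear 5S ribosomal RNA at 7196 RPM, ACGGTCGACCTTGAGTTTCGGC at 28.7 RPM and ACGGTCTACCATGAGTTTCGGC at 25.4 RPM. In the pistil of stage 0 they were miR395 at 0.0220 RPM (1 read), GAATTCCACCACGTTCCCGTGG at 5.12 RPM and GATAGGAGGATACAGTTAAAACTC at 0.132 RPM. In the pistil of stage 3 it was miR319 at 2298 RPM.

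A difference in slope over stages 0 to 2 between anther and pistil was found by edgeR in 7 of 6270 tags. The animal miR-21 stood at 0.285 RPM in the pistil of stage 0, above the floor of 0.0659 RPM.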

How the results depend on the processing

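The alternatives without the stop oligo, those of the contig test, its 100000 shuffles and the family slopes, and the fits of stages 0 to 2 without a block were chosen only after the data were seen. Of the alternatives of the counts and values that answer a comparison, 118 kept direction and side of the threshold (counts within 1.5 times), 16 were stronger and 25 weaker. Of those of single named items, 459 kept both, 42 were weaker, 4 stronger and 1 reversed. The reversed one was miR403, with a log2 fold change of -2.01 without anther replicate 4 against 1.01, and up to 2.02 without another library. Its cause was that library's 569 reads. For the rest the cause was not tested.

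Within the stage-named libraries, with fewer samples, 0 of the 12 base shares, 1 of the 2 duplex classes and 13 families passed. DESeq2 called 13 families for tissue, 14 over anther length and 5 over pistil stage, and 1398 tags over length and 1457 over pistil stage. TMM factors gave 873 tags and 0 families over pistil stage. A filter of 2 RPM gave 14888 tags for tissue, with more tags tested, and 50 RPM gave 170 for tissue, 5 over length and 25 over pistil stage, with fewer tested. The correlation of the 24-nt share with length was 0.836 over distinct tags (exact permutation p = 0.0417), where length runs along the batches. With the naming series as a factor 1 family had a slope over length.

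With stage number as a block (anther and pistil paired by stage) in stages 0 to 2, 11 families, 1659 tags and 555 contigs differed. Leaving out 1 library at a time gave 0 to 0 length classes, 0 to 8 base shares, 1 to 2 duplex classes, and a correlation of -0.759 to 0.817. It gave 8 to 13 families, 1736 to 2073 tags and 585 to 642 contigs for tissue. The ranges for slopes were 0 to 415 tags and 1 to 6 families over length, and 0 to 2072 tags and 0 to 2 families over pistil stage. The planned edgeR alternatives of phased contigs gave no value, since 0 contigs were phased, and 100000 shuffles gave 2. Depth set a floor of 0.0440 to 0.0982 RPM per library.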

Other observations

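The tests of register in this part were chosen only after the results were seen.

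Fragments of stable RNAs differed in level between libraries beyond the microRNA families. Nuclear 5.8S ribosomal RNA ran from 4456 RPM (pistil stage 3) to 15857 RPM (pistil stage 1), with leaf and bud between, and plastid 16S ribosomal RNA at 3034 RPM in leaf against 231 to 723 RPM in the other 12 libraries. In leaf, miR396 stood at 6757 RPM and miR393 at 868 RPM, above the highest anther or pistil library (2121 and 259 RPM) though under 4-fold for each. In the bud, which held anthers of <1.0 mm, miR319 stood at 728 RPM, between the highest anther (212 RPM) and the lowest pistil (919.9 RPM), and miR159 at 1875 RPM, likewise between the tissues (447 and 3013 RPM).

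Beyond the 2 contigs that passed with 100000 shuffles, anther contigs might carry a 24-nt register too weak to pass singly. Among the 228 contigs higher in anther, 22 (9.65%) had an unadjusted p under 0.05 at 24 nt, against 5.34% of those lower in anther and 4.77% of those not past the threshold (Fisher's exact two-sided p = 0.0120 against both together, odds ratio 2.01). Of the 66 at least 8-fold higher, 11 did (odds ratio 3.57, exact p = 0.00117). Both phased contigs are in these counts, and without them 20 of 226 did against 5.03% of the others (odds ratio 1.83, exact p = 0.0373), and 9 of 64 (odds ratio 2.92, exact p = 0.0091). In shuffles repeated for spacings of 20 to 28 nt, 24 nt gave 23 of the 228 contigs (21 without the phased pair), and each other spacing at most 12. The 412 contigs lower in anther gave 22 at 24 nt, 18 at 28 nt and 10 to 15 at the other 7 spacings, so 24 nt was their highest count too. The hypothesis rests on contigs chosen from the same libraries. Fisher's tests count each contig as independent, though how many loci the contigs come from is not known, so their p-values may be too low.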
